A study of Drosophila melanogaster with 2 samples.

How the data were processed

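The study holds 1 group: whole, mixed-sex Drosophila melanogaster embryos aged 0 to 24 hours, from a transgenic line with NC2alpha fused to eGFP at its C terminus. Chromatin bound by the fusion protein was precipitated with an anti-GFP antibody and sequenced in 2 biological replicates. No condition or stage was compared, and no paired analysis was possible because all libraries belong to 1 group.

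Per the file headers and the notes deposited with the lists, the authors called peaks on each replicate and on pooled replicates against a control alignment, kept relaxed lists of peaks and background as input for the irreproducible discovery rate (IDR), and derived from them an optimal list that passed an IDR threshold. The lists were deposited on the builds dm3 and dm6. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' score relative to the control, used as deposited; its scale is not given in the sources used here. The -log10 q value per peak was used as deposited by the authors and was at its maximum of 3.59 in 89.5% of optimal peaks on dm6, so peaks were ranked by signal. The summit offset (other) was used as deposited by the authors to place each summit, and the p-value column holds -1 throughout. The optimal list was made of exactly the strongest pooled peaks by signal: 2174 of 2174 on dm6 and 2020 of 2020 on dm3. Replicate lists on dm6 held 30000 peaks each, and their length is set by how many were kept, not by depth. On dm3 the replicate lists held 30000 and 27113. Sequencing depth is unknown, since reads were not used here, and no interval covers it. The pooled signal was 1.00 times the sum of the replicate values at the median.

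Coordinates were analysed on dm6, counted from 1, with the Release 6 reference sequence and Ensembl release 115. dm3 lists were only counted and described. The 6 chromosomes with optimal peaks (2L, 2R, 3L, 3R, 4 and X) hold 18164 genes, of which 13945 are protein-coding, and 23581 TSS positions. A peak was assigned to every gene with an annotated TSS within 500 bp of its summit. The representative TSS of a gene was the one with the most transcripts, and the most upstream of these. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

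The share of summits at TSSs was compared with 1000 random placements on the same chromosomes (one-sided), and feature classes with 10870 random positions. Replicate lists were compared as their 2174 strongest peaks, overlapping by at least 1 base, against 1000 circular shifts. Each replicate value of an optimal peak was that of the strongest overlapping peak in that replicate's list. Binomial intervals are exact (Clopper-Pearson) at 95%, and cover counting error only.

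Gene lists numbered 26: ribosomal proteins, mitochondrial ribosomal proteins, translation factors, proteasome, oxidative phosphorylation, glycolysis, general transcription machinery, cell cycle, replication-dependent histones, small nuclear RNAs, small nucleolar RNAs, transfer RNAs, heat shock proteins, homeotic complex genes, segmentation genes, dorsoventral patterning genes, early zygotic genes, Enhancer of split complex, muscle, neural and glial, hemocyte and fat body, germline, cuticle proteins, chorion, vitelline and yolk proteins, testis-specific genes and chemoreceptors. Of the symbols written for them, 6 matched no gene and 6 were matched through older symbols. Cp110 and Cp190, caught by a name pattern, and Tdrd3 and svp, caught by a synonym, were left out before outcomes were seen. Each list was tested with Fisher's exact test (two-sided, conditional odds ratio) against the other protein-coding genes, or against all other genes for the 3 RNA lists, with Benjamini-Hochberg adjustment over the 26 lists and a threshold of 0.05. Chromosomes were tested the same way over 6 tests.

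Core promoter motifs were searched in 13691 protein-coding promoters with distinct representative TSSs: TATA box (STATAWAW, -45 to -20), Initiator (TCAKTY, -12 to 8), DPE (RGWYV, 28 bases downstream of an Initiator), TCT (YYCTTTYY, -12 to 8), MTE (CSARCSSAAC, 10 to 30, up to 2 mismatches), pause button (KCGRWCG, 15 to 55), DRE (WATCGATW, -150 to 50), Ohler 1 (GGTCACAC, -80 to 50), Ohler 6 (GTATWTTT, -150 to 50), Ohler 7 (CATCNCTA, -80 to 50), E-box (CAGCTG, -150 to 50) and GAGA (GAGAGAG, -150 to 50). Promoters with a summit within 500 bp of the representative TSS were compared with all others by Fisher's exact test (two-sided), adjusted over 12 motifs. Signal of bound promoters with and without each motif was compared by a permutation test of medians (two-sided, 100000 resamples).

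The genes, lists, motifs, tests and named-gene rule, and all alternatives not marked as added, were fixed before the data were examined. The rule named the genes nearest to the 25 strongest peaks at TSSs, the 5 strongest peaks more than 1000 bp from any TSS, NC2alpha, NC2beta, Tbp, Trf and Trf2, every gene of the homeotic complexes, the 4 bound members with the highest signal in each called list with up to 4 unbound members of lists of at most 30 in alphabetical order, and the 3 bound genes with the highest signal for each called motif.

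Alternatives were 200 and 1000 bp to a TSS, the 1087 strongest peaks, the 4348 strongest pooled peaks, leaving out each replicate, assigning only the gene of the nearest TSS, comparing only genes or promoters with a pooled peak before the filter, stratifying by GC content of 250 bp to either side of the TSS in 10 strata (Mantel-Haenszel), motif windows moved 500 bp upstream, 1 more mismatch, other rules of overlap and dm3 for the replicates. Alternatives added after the data were seen were motifs without ribosomal protein genes, RNA lists against other non-coding genes, and odds ratios divided by their median over 1000 sets of peaks placed at random genes, with offsets drawn from the observed summits.

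The tests of lists, motifs, chromosomes, replicate overlap, share at TSSs, signal by motif and words were tested on simulated data. Other tests, such as those of summit position by promoter class, GC content and transfer RNA genes between replicates, were not. With peaks placed at random genes among 18164 and 20 sets per setting, Fisher's test called planted ribosomal protein, proteasome and chemoreceptor differences in 20 of 20 sets each. The same held for planted differences of TATA box and Ohler 1 promoters and of chromosome X. With nothing planted, Fisher's test made 13 calls in 520 list tests, 20 in 240 motif tests and 9 in 120 chromosome tests. The comparison with random genes made 0, 3 and 4 such calls. It called the planted differences of the lists and of chromosome X in 19 of 20 sets each, and those of both motifs in 20 of 20. A planted overlap of 60% between lists of 2000 peaks was measured as 60.25 to 60.65%, and the share at TSSs differed from the planted share by at most 1.44 percentage points in 20 sets. Signal planted 1.5-fold higher at DRE promoters was called in 5 of 5 sets, with 0 calls among 60 tests with nothing planted, over 13691 promoters. A planted word was called in 5 of 5 sets among 8192 words, and 0 words were called in 5 sets with nothing planted.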

Results

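NC2alpha is the subunit of negative cofactor 2 that pairs with NC2beta on TATA-binding protein. Its eGFP-tagged form was mapped by anti-GFP ChIP-seq in whole, mixed-sex embryos aged 0 to 24 hours, in 2 biological replicates. The deposited list of peaks that passed the authors' reproducibility filter (the optimal list) held 2174 peaks on Release 6 of the Drosophila melanogaster genome (dm6), and genes were taken from Ensembl 115. Signal below is the authors' value per peak, whose scale is not given in the sources used here, and it ranks peaks within a list.

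The strongest peak lay at plexus (px, FBgn0003175; 2R, 22514131 to 22514486), with a signal of 1230.2, and its replicate values were 658 and 566. Ugalt (signal 1094; X, summit 2703885), CG14100 (1083; 3L, summit 19590620) and Chro (919; 3L, summit 22878896) followed among the peaks within 500 bp of a transcription start site (TSS). The Chro summit lay 88 bp downstream of a TSS of that gene and -193 bp from a TSS of Ssl1, and the next strongest peaks lay at ph-p (894), CG1888 (876), lncRNA:CR31840 (866), PNPase (782), Art3 with mRpS10 (778) and CG18549 (717). The remaining members of the strongest 25 were at lncRNA:CR44619, CenG1A with mRpS23, gish, mRpL41, CG9147 with Fbw5, Sox14, CG31145, larp, Pdrg1, lncRNA:CR31044, Tcs5, CG5098, Fkbp14, Rtnl1 and Shc, down to a signal of 507. At 24 of the 25 the replicate values were within 2-fold of each other; the exception was lncRNA:CR31840, with 605 in replicate 1 and 268 in replicate 2.

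Of the 2174 summits, 1192 (54.8%; exact 95% binomial interval 52.7 to 56.9) lay within 500 bp of an annotated TSS. Random placement on the same chromosomes gave a mean of 13.7% and at most 15.9% in 1000 sets (4.02-fold; one-sided permutation p = 0.000999, the smallest these sets can give). Among summits at TSSs the median position was -77 bp relative to the nearest TSS (quartiles -173.5 and -1), on the upstream side, and 450 of the 2174 peaks (20.7%) lay at TSSs of at least 2 genes. Summits fell in 5' UTRs in 13.1% of cases against 3.28% of random positions, and in coding sequence in 0.966% against 16.5%. Introns held 43.3% of summits against 43.1% of random positions, intergenic sequence 37.9% against 30.3%, 3' UTRs 1.38% against 5.01% and exons of non-coding genes 3.45% against 1.76%. The share at TSSs was 60% in peaks ranked 1 to 500, 53.0% in those ranked 1001 to 2174 and 21% in the weakest 10000 of the 30000 peaks called on pooled replicates before the filter. In all 1604 genes had a peak at a TSS, of which 1460 were among the 13945 protein-coding genes (10.5%) and 116 among the 3261 genes annotated as ncRNA (3.56%).

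**Figure D1:**
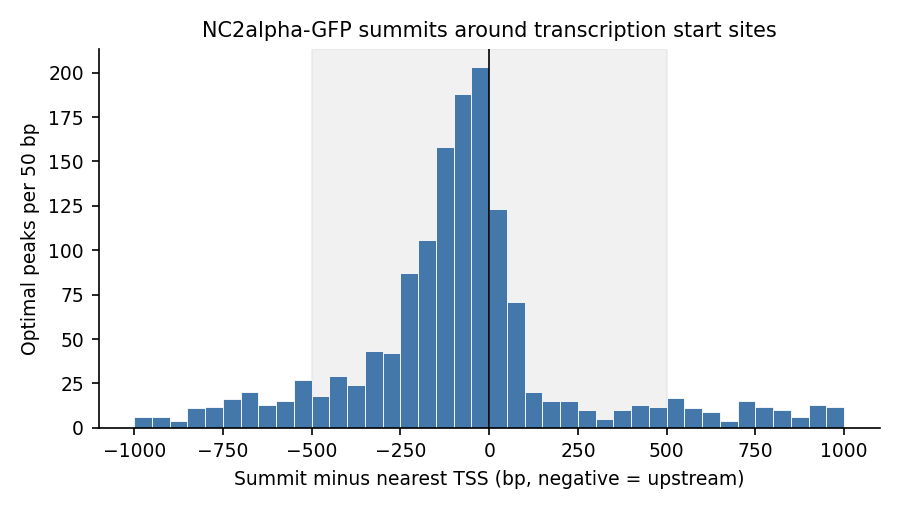
Number of optimal peaks per 50 bp (vertical axis) by distance of the summit from the nearest TSS in bp (horizontal axis, negative upstream); the shaded range is 500 bp to either side. Summits gather just upstream of the TSS, with a median of -77 bp among the 1192 in the shaded range.

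**Figure D2:**
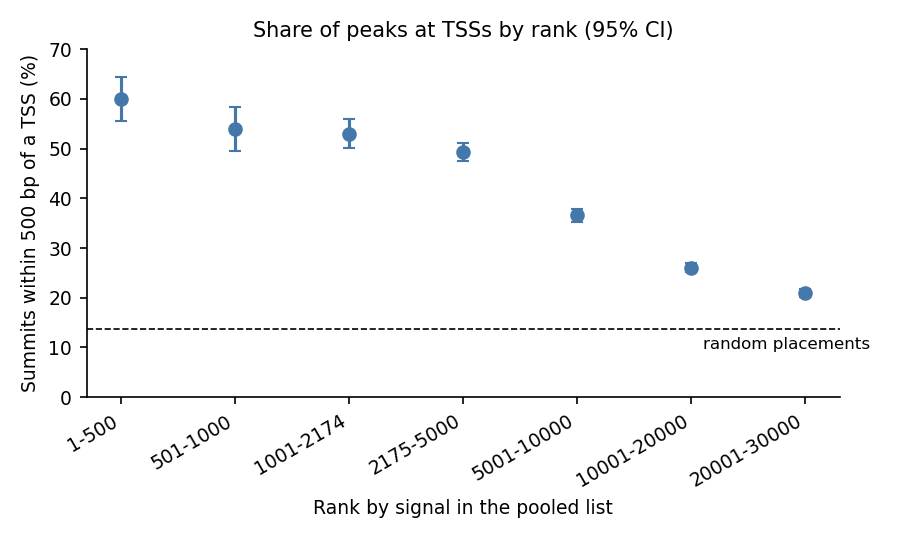
Percentage of summits within 500 bp of a TSS (vertical axis, points with exact 95% binomial intervals) by rank of signal in the list called on pooled replicates (horizontal axis); the dashed line is the mean of random placements, 13.7%. The share falls from 60% in the strongest 500 peaks to 21% in the weakest 10000.

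Away from TSSs, the strongest peak lay in an intron of u-shaped (ush; 2L, 480910 to 481271; signal 1111, replicates 590.2 and 522), at -1405 bp from the nearest TSS, that of cabut (cbt). An intron of CG11050 (2L, summit 6612722; 871) and the interval between Su(z)2 and CG13323 (2R, summit 13035339; 862; 11917 bp from the nearest TSS) held the next peaks. Introns of canoe (cno; 3R, summit 5215527; 685) and Lrch (2L, summit 17378863; 626) completed the strongest 5. Both of the last 2 were stronger in replicate 1, at 468 against 216 for cno and 417 against 213 for Lrch. In total 743 peaks (34.2%) had a summit more than 1000 bp from any TSS.

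The NC2alpha gene itself had a peak (signal 369.7, rank 76; replicates 201 and 185), with its summit -93 bp from a TSS (gene at 2R, 21670152 to 21671593). The line carries a tagged copy of this gene, and reads from the copy and from the native gene cannot be separated in peak lists. NC2beta, Tbp and Trf had no peak at a TSS, neither in the optimal list nor among the 30000 pooled peaks before the filter, and Trf2 had only a peak before the filter (66.8). Of the 12 genes of the homeotic complexes, bcd alone had an optimal peak at a TSS (133; replicates 84.7 and 52.7; summit -204 bp from the TSS). Antp held 3 optimal summits inside the gene, none of them at a TSS. Before the filter, peaks at TSSs were present for Dfd (73.2), Ubx (53.0), Scr (46.0), Abd-B (36.9), abd-A (34.2) and Antp (31.05), and for none of lab, pb, zen, zen2 and ftz.

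The strongest pooled peaks at TSSs, at px, Ugalt and CG14100, had replicate values of 658 and 566, 574 and 528, and 544 and 543. Choosing sites by pooled signal favours high values in both replicates. The strong peaks at lncRNA:CR31840 (605 and 268) and cno (468 and 216) were less alike. When the 2174 strongest peaks of each replicate were compared, 67.2% of those of replicate 1 overlapped one of replicate 2, and 66.4% the reverse. Circular shifts of one list gave a median of 1.196% and at most 2.07% (1000 shifts, one-sided permutation p = 0.000999, the smallest they can give). Across the 2158 optimal peaks with a value in both replicates, which are not independent replicates, Spearman's rho was 0.533. Of 27826 pooled peaks outside the optimal list, 13019 had a value in both replicates, and across these rho was 0.316. Replicate 1 had the higher values (medians 69.96 and 53.2; median ratio 1.31). After scaling for that ratio, the standard deviation of the log2 ratio was 0.64, and 255 peaks were over 2-fold apart.

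**Figure D3:**
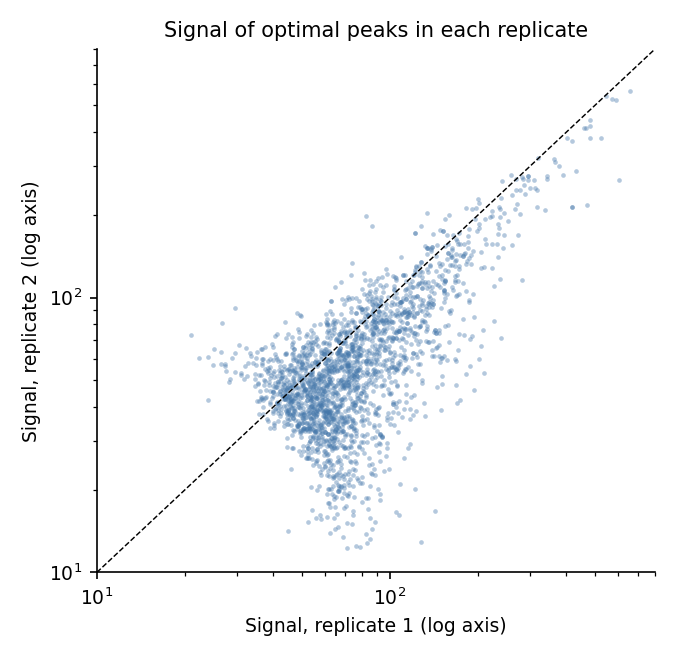
Signal of each optimal peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis); each point is 1 of the 2158 peaks with both values and the dashed line marks equal values. Most points lie below the line, with a median ratio of replicate 1 over replicate 2 of 1.31.

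Ribosomal protein genes carried NC2alpha most often: 54 of 93 had a peak at a TSS (58.1%, against 10.2% of the other protein-coding genes; odds ratio 12.3, 95% interval 7.93 to 19.1, adjusted exact p = 5.27e-28). RpS27 (437), RpL7 (381), RpL14 (341) and RpS10b (297) had the highest signals, and 30 of the 54 peaks also lay at a TSS of another protein-coding gene. Before the filter 82 of the 93 had a peak, but that relaxed list includes background. Lists that were not called ranged widely in it, from 26 of 32 proteasome and 25 of 30 cell cycle genes to 3 of 27 testis-specific genes. In glycolysis, 6 of 12 genes had a peak (odds ratio 8.58, 2.29 to 32.1, adjusted exact p = 0.00299), led by Gapdh2 (239), Hex-A (223), Pgk (177) and Ldh (150), whereas Ald1, Gapdh1, Pfk and Pgi were among the 6 without one. The Enhancer of split complex had peaks at 5 of 11 genes (odds ratio 7.15, 1.72 to 28.1, adjusted exact p = 0.0109), at E(spl)m3-HLH (135), E(spl)malpha-BFM (118), E(spl)mbeta-HLH (117), E(spl)m2-BFM (93.2) and E(spl)m7-HLH, and none at E(spl)m4-BFM, E(spl)m5-HLH, E(spl)m6-BFM and E(spl)m8-HLH among the 6 without. Its call rested on details of the peak set: the odds ratio was 3.12 without replicate 1 (adjusted exact p = 0.218), 5.02 without replicate 2 (0.0650), 4.58 at 200 bp (0.107) and 1.65 in the 1087 strongest peaks (0.693). Both it (3.91, adjusted exact p = 0.124) and glycolysis (4.69, 0.0770) lost their call when only genes with a peak before the filter were compared. All 11 Enhancer of split genes lie between 25997621 and 26041008 on 3R. Fisher's test counted these neighbours as separate genes, so its p for this list may overstate the evidence.

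Bound ribosomal protein genes also had a higher signal than other bound protein-coding genes, with a median of 154 against 122 (permutation p = 0.00300, adjusted 0.00900 over the 3 enriched lists, a comparison chosen after the data were seen). The corresponding adjusted p was 0.196 for glycolysis (medians 164 and 123; permutation test) and 0.813 for the Enhancer of split genes (117 and 124; permutation test).

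No peak lay at a TSS of the 179 chemoreceptor genes (upper limit of the odds ratio 0.176, adjusted exact p = 5.01e-08), the 113 cuticle protein genes (0.282, 4.58e-05) or the 111 replication-dependent histone genes (0.287, 4.58e-05). The histone genes are repeated copies and had no peak before the filter either, so an effect of read mapping is open for them. All of them lie between 21416953 and 21541681 on 2L, and Fisher's test counted neighbouring copies as separate genes. Its p for the histone list therefore overstates the evidence. Among genes with any peak before the filter, the adjusted exact p was 0.124 for chemoreceptors and 0.0683 for cuticle proteins, still with no peak. Transfer RNA genes had peaks at 8 of 295 (odds ratio 0.284, 0.121 to 0.569, adjusted exact p = 1.53e-04), the strongest at tRNA:Tyr-GTA-1-8 (382), tRNA:Phe-GAA-1-2 (180.3), tRNA:Gln-TTG-2-1 (162) and tRNA:Glu-TTC-1-5 (152), and for 6 of the 8 the peak was also at a TSS of a protein-coding gene. The 8 genes had 7 distinct peaks, with 0 summits within 100 bp of the TSS. Only 57 transfer RNA genes are of unique sequence, so an effect of read mapping is open for this list too. Small nucleolar RNA genes had peaks at 11 of 274 (odds ratio 0.428, 0.211 to 0.781, adjusted exact p = 0.00955), led by snoRNA:U49:66Da (341), snoRNA:Or-aca5 (213), snoRNA:Psi28S-2949 (213) and snoRNA:Or-CD11a (198). These were shared peaks: the snoRNA:U49:66Da peak was that of RpL14, with its summit -496 bp from the snoRNA TSS, and snoRNA:Or-aca5 and snoRNA:Psi28S-2949 had 1 peak between them. The 11 small nucleolar RNA genes had 10 distinct peaks, 5 had a peak that was also at a TSS of a protein-coding gene, and the summits lay at a median of -375 bp, with 0 within 100 bp. Both RNA calls were relative to all genes: against other non-coding genes, a comparison added after the data were seen, the odds ratios were 0.776 (adjusted exact p = 0.618) for transfer RNAs and 1.199 (0.618) for small nucleolar RNAs. Many genes of both lists lie in clusters, which Fisher's test counted gene by gene, so its p may overstate the evidence here too. Without replicate 2 the transfer RNA odds ratio was 1.08 (adjusted exact p = 0.841), and that call also ended in the 1087 strongest peaks (0.546, 0.321) and the 4348 strongest pooled peaks (0.701, 0.0918). The small nucleolar RNA odds ratio was 0.111 at 200 bp and turned to 1.38 at 1000 bp (adjusted exact p = 0.214). That call also ended without replicate 1 (0.581, adjusted exact p = 0.110), without replicate 2 (0.509, 0.0577), in the 1087 strongest peaks (0.590, 0.449), among genes with a peak before the filter (0.615, 0.446) and with stratification by GC content (0.467, 0.0531).

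The other 18 lists stayed above the threshold of 0.05. Heat shock genes had peaks at 5 of 20 (Hsp83 268, Hsp68 228, Hsc70-4 169.7, Hsp26 162, Hsp27 139.7; adjusted exact p = 0.124), translation factors at 10 of 52 (0.127), mitochondrial ribosomal proteins at 13 of 73 (0.124), general transcription machinery at 9 of 45 (0.124), small nuclear RNAs at 6 of 32 (0.126), cell cycle genes at 6 of 30 (0.229), the proteasome at 6 of 32 (0.243) and oxidative phosphorylation at 9 of 84 (1). Without replicate 1, heat shock genes (odds ratio 3.58), translation factors (2.51) and mitochondrial ribosomal proteins (2.35) passed the threshold. At 200 bp, heat shock genes (4.08), small nuclear RNAs (3.55) and general transcription machinery (3.07) passed it, and with only the gene of the nearest TSS heat shock genes (4.01) and small nuclear RNAs (3.36). In the 1087 strongest peaks, heat shock genes (5.53) and translation factors (3.02) passed it. In the 4348 strongest pooled peaks, cell cycle genes (3.31), translation factors (2.71), general transcription machinery (2.39) and mitochondrial ribosomal proteins (2.26) passed it, and hemocyte and fat body markers, with no peak, were depleted (adjusted exact p = 0.0476). Developmental lists had peaks at 6.25% to 15% of their genes, against 10.5% of protein-coding genes: segmentation 3 of 29 (wg, oc, hry), dorsoventral patterning 3 of 25 (cact, rho, ush), early zygotic genes 1 of 16 (Sxl), genes of the homeotic complexes 1 of 12 (bcd), muscle 3 of 20 (sls, Msp300, how), neural and glial 2 of 20 (moody, elav) and germline 2 of 17 (bgcn, orb). Testis-specific genes had 1 of 27 (Mst36Fa), and there was none at the 20 hemocyte and fat body markers or the 17 chorion, vitelline and yolk protein genes. With 30 members or fewer, intervals were wide: the upper limit of the odds ratio was 5.35 for genes of the homeotic complexes and 1.73 for hemocyte and fat body markers. Genes named here and E(spl)m7-HLH were added to the naming rule after their values were seen, because 5 or fewer of the list had a peak.

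**Figure D4:**
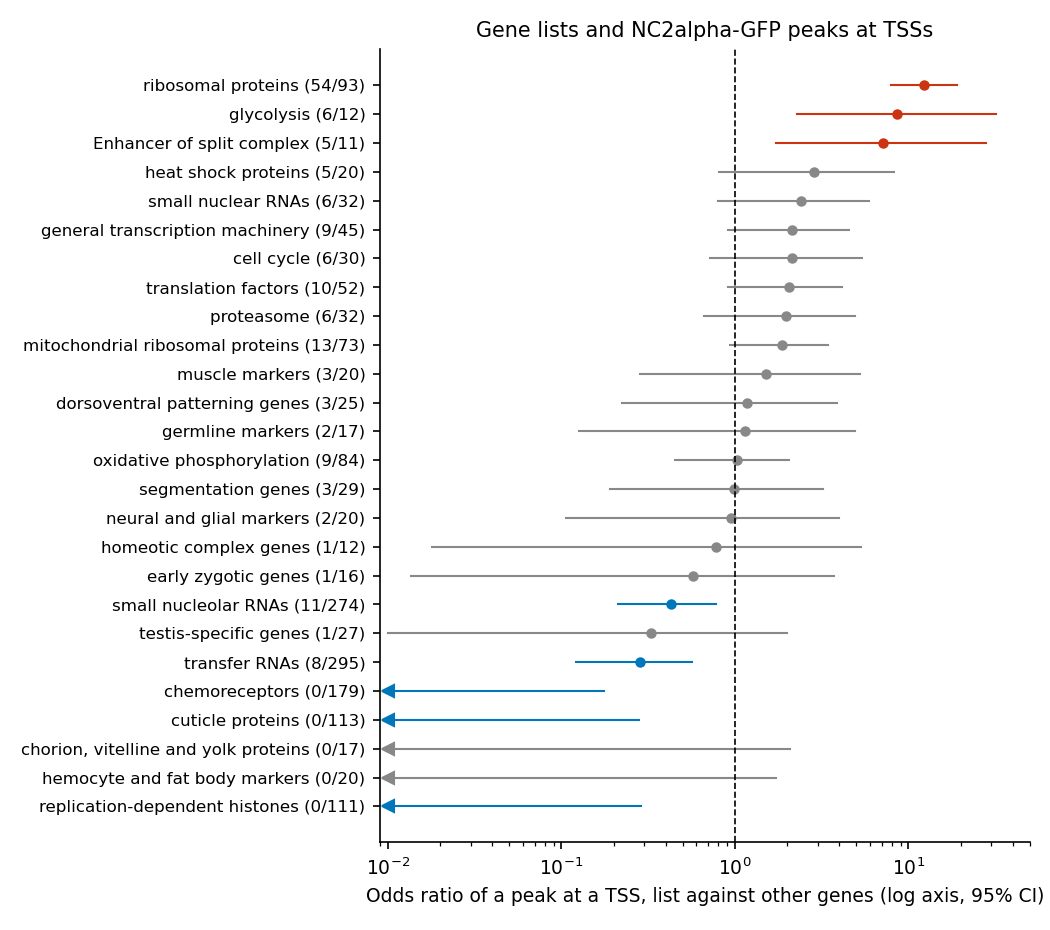
Odds ratio of having a peak at a TSS (horizontal, log axis; points with 95% intervals) for 26 gene lists against other genes, with members with a peak and members tested in brackets; arrows mark odds ratios of 0, red and blue adjusted p under 0.05. Ribosomal proteins (12.3) stand highest, and 5 lists lie below 1 past the threshold.

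NC2alpha promoters were poor in TATA boxes: 2.88% of 1216 bound promoters had one, against 7.69% of 12475 others (odds ratio 0.356, adjusted exact p = 3.26e-11). Sulf1 (351), Thor (256) and scyl (244) had the highest signals among bound TATA promoters. The TCT initiator was found in 3.54% against 0.890% (odds ratio 4.08, adjusted exact p = 3.13e-11), with RpL14, RpS10b and CG13501 (282) the strongest. The Ohler 7 motif was in 8.55% against 3.70% (2.43, 5.06e-12), strongest at mRpL41 (643), Mkk4 (416) and Brf (232), and the E-box in 19.2% against 13.9% (1.47, 3.54e-06), strongest at mRpL41, CG9147 and Fbw5. The DNA replication-related element (DRE) was in 18.7% against 13.6% (1.45, 8.60e-06), strongest at mRpS23, CG9147 and Fbw5, and GAGA in 7.32% against 4.54% (1.66, 8.24e-05), strongest at bves (399), CG11151 (344) and Fhos (326). The pause button (5.59% against 3.99%; 1.42, 0.0151; Sox14, CG31145, Fkbp14) and Ohler 6 (7.15% against 5.32%; 1.37, 0.0151; Ssl1, mRpS10, mRpL41) were enriched less. The Initiator (odds ratio 0.895, adjusted exact p = 0.264), DPE (0.813, 0.310), MTE (1.17, 0.160) and Ohler 1 (1.15, 0.264) were not called. Peaks placed at random genes, added after the data were seen, gave median odds ratios of 1.21 for Ohler 7, 1.19 for DRE and 1.10 for the E-box. They gave 0.905 for GAGA, 0.899 for the pause button and 0.898 for TATA. The motif calls held against these sets, while Fisher's test made 20 calls in 240 simulated motif tests with nothing planted.

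Of the 43 bound promoters with TCT, 33 belonged to ribosomal protein genes. With those genes left out, an alternative chosen after the data were seen, TCT was no longer enriched (odds ratio 1.18, adjusted exact p = 0.591). Without replicate 1 the Initiator was depleted (0.773) and Ohler 1 enriched (1.27), and without replicate 2 MTE was enriched (1.32). Among promoters with any peak before the filter, only TCT (3.98) and Ohler 7 (1.52) stayed enriched, TATA was 0.671 (adjusted exact p = 0.0678), DRE 0.972 and Ohler 1 depleted (0.680, 0.00401). DRE also ended with only the gene of the nearest TSS (1.16, adjusted exact p = 0.177), as did Ohler 6 (1.18, 0.298), in the 1087 strongest peaks (1.22, 0.0954), as did Ohler 6 (1.35, 0.0926), and with 1 more mismatch (1.09, 0.187). At 200 bp, GAGA (1.22, adjusted exact p = 0.259), the pause button (1.27, 0.208) and Ohler 6 (1.34, 0.0554) ended, and the Initiator (0.727, 0.00799) and DPE (0.580, 0.0491) were depleted. In the 4348 strongest pooled peaks the Initiator was depleted (0.820) and Ohler 1 enriched (1.64), which it also was with 1 more mismatch (1.30), and MTE was enriched in the 1087 strongest peaks (1.33). Peak signal differed by motif for 0 of 12 motifs in permutation tests; 1 had an unadjusted p under 0.05, the E-box, with medians of 129 and 119 (p = 0.0247, adjusted 0.291). In peaks among the strongest 2174 of both replicates, 0 of 12 differed as well; the E-box had medians of 149 and 145 (permutation p = 0.706), and the 1 with an unadjusted p under 0.05 was TCT, with 181 and 146 (permutation p = 0.0284, adjusted 0.341).

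**Figure D5:**
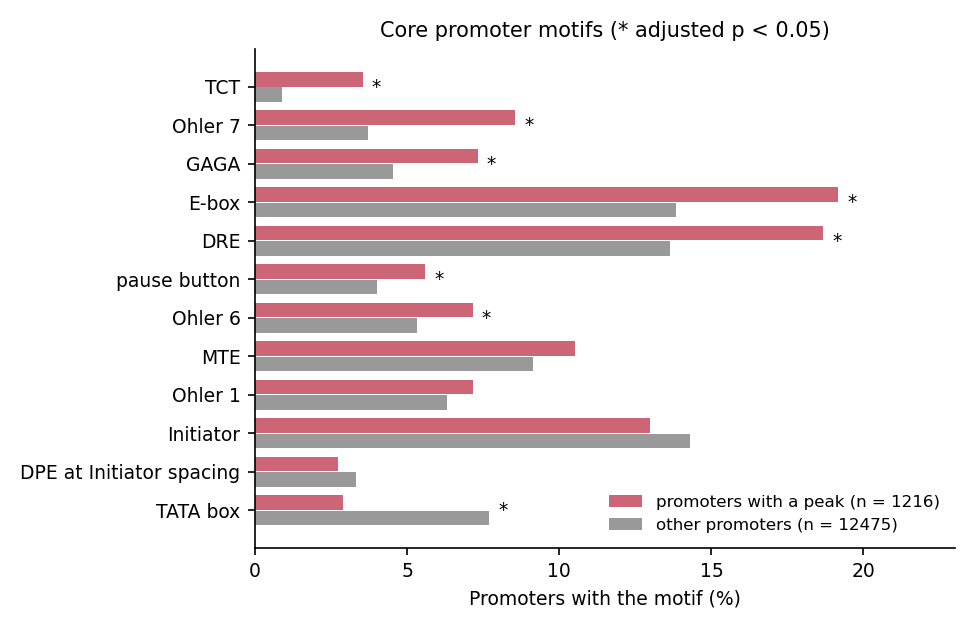
Percentage of promoters with each core promoter motif (horizontal axis) among 1216 protein-coding promoters with a peak and 12475 others; asterisks mark adjusted p under 0.05. TATA boxes are rarer in bound promoters (2.88% against 7.69%) and 7 motifs are more frequent.

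Protein-coding genes on 3R had a peak more often (12.04% against 9.96% elsewhere; odds ratio 1.24, adjusted exact p = 0.00391) and those on X less often (8.65% against 10.8%; 0.782, 0.00709). The small chromosome 4 had peaks at 4 of 80 genes (0.449, adjusted exact p = 0.280), and 2L (0.974), 2R (0.919) and 3L (1.07) were not called. Neither call held with only the gene of the nearest TSS (3R 1.16, adjusted exact p = 0.232; X 0.880, 0.490), and X lost its call without replicate 1 (0.850, adjusted exact p = 0.116). Against peaks placed at random genes, a comparison added after the data were seen, neither was called (3R 1.18 and X 0.813 times the random median, adjusted permutation p = 0.0899 for both), and Fisher's test made 9 calls in 120 simulated chromosome tests with nothing planted.

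The authors' list on the older build dm3 held 2020 peaks (dm6 over dm3, 1.08), with a median signal of 123 against 118 on dm6, and 404 bp was the commonest width on both. The highest signal was 1230.2 on both builds.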

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

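The comparisons without ribosomal protein genes, with other non-coding genes and with peaks placed at random genes were chosen only after the result was seen; the other alternatives were planned. Unless a cause is given, the cause was not tested.

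The share of summits at TSSs had the same direction and a permutation p of 0.000999, the smallest possible, under each alternative. With a summit within 200 bp, 5 lists were enriched, 4 motifs enriched and 3 depleted. At 1000 bp the small nucleolar RNA odds ratio turned to 1.38. In the 1087 strongest peaks, 876 genes had a peak, fewer because fewer peaks were used, and 3 lists were depleted. In the 4348 strongest pooled peaks, 2915 genes had a peak, more because more were used, 7 lists were enriched and 2 motifs depleted. With only the gene of the nearest TSS, 5 lists were enriched and 0 chromosomes called. Among genes with a pooled peak before the filter, 1 list was enriched and 1 depleted. Among promoters with such a peak, 2 motifs were enriched, and the odds ratio turned to 0.972 for DRE and 0.680 for Ohler 1. With motif windows moved 500 bp upstream, where motifs of the core promoter are not placed, 0 motifs were enriched and 0 depleted, and odds ratios turned to 1.09 for TATA, 0.931 for Ohler 6 and 0.668 for Ohler 7. The correlation of replicate signals outside the optimal list was 0.316 among peaks with a value in both replicates.

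Leaving out 1 replicate gave 2 to 5 enriched lists, 3 to 4 depleted lists, 1 to 2 depleted motifs and 1 to 2 called chromosomes, and a transfer RNA odds ratio of 0.314 to 1.08. Divided by their median over peaks placed at random genes, the 3 enriched and 5 depleted lists and the TATA depletion held, 8 motifs were enriched, MTE (1.27) joining the 7, and 0 chromosomes were called (3R 1.18, X 0.813, adjusted p of 0.0899 for both). Neighbouring histone copies, Enhancer of split genes and clustered RNA genes were counted as separate genes in that comparison too. Against other non-coding genes, the small nucleolar RNA odds ratio was 1.199.

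Of 261 single-list alternatives, 226 kept direction and side of the threshold, 16 fell short of it, 16 newly passed it and 3 reversed. For motifs these were 122, 19, 10 and 5 of 156, and for chromosomes 49, 5, 0 and 0 of 54. The first of these counts include odds ratios not called in either setting that moved across 1, namely 32, 10 and 7. Of 76 alternatives for counts and shares, 55 were within the spread or 1.5 times and 21 were not. Depth limits were not assessed, since reads were not used here.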

Other observations

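All comparisons here were chosen after the data were seen; among the tests of explanations, those of words in alternating peaks and of repeated sequence were chosen only after the result was seen.

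The position of NC2alpha relative to the TSS differed between promoter classes. At bound promoters with a TATA box the median summit lay -14 bp from the representative TSS, against -109 bp at the others (35 and 1181 promoters; permutation p adjusted over 17 classes = 0.00374). Ribosomal protein promoters had a median of -29.5 bp against -115 bp (adjusted permutation p = 0.00136), and 90.7% of their summits lay within 100 bp of the TSS against 37.4% elsewhere. TCT promoters had -41 against -110 bp (adjusted permutation p = 0.0150). Of the 43 bound TCT promoters, 33 belonged to ribosomal protein genes, so these 2 shifts overlap, and TCT promoters of other genes were not tested alone. Farther upstream than the other promoters lay Initiator promoters (-148.5 against -103 bp, 0.00442), DPE promoters (-180 against -105 bp, 0.0150) and GAGA promoters (-153 against -104 bp, 0.0150; permutation tests). In peaks of each replicate alone, TATA promoters had -3 against -93 bp (replicate 1) and -13.5 against -127 bp (replicate 2), and ribosomal protein promoters -20 against -97.5 bp and -41.5 against -131 bp. The upstream shift was carried mainly by replicate 2: GAGA promoters had -88.5 against -91 bp in replicate 1 and -197 against -122 bp in replicate 2, and DPE promoters -104 against -91 bp and -203 against -123 bp.

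Against other non-coding genes alone, small nuclear RNA genes were enriched: 6 of 32 (18.8%) had a peak, against 138 of 4187 (3.30%, odds ratio 6.76, 2.24 to 17.2, exact p = 6.19e-04, adjusted over 3 lists 0.00186). The list was not called against all other genes (odds ratio 2.39, adjusted exact p = 0.126). Nor was it called against peaks placed at random genes (2.36 times the random median, adjusted permutation p = 0.179). The 6 bound genes were snRNA:U1:95Ca (signal 128), snRNA:U2:34ABb (122), snRNA:7SKa (107), snRNA:U1:21D (94.3), snRNA:U4:39B (93.7) and snRNA:U5:63BC (85.9), the last the only one with the higher value in replicate 2, and their summits lay 10 to 196 bp downstream of the TSS. Several genes held many summits: lncRNA:CR44357 had 10, a count that overlaps the 9 of CG1677, which lies inside it. Summits numbered 9 in kirre (0.228 per 10 kb), 8 in Raf (1.65 per 10 kb) and ush (1.24), and 7 in CHES-1-like (2.59), Eip75B (0.615) and Hr4 (1.06), with all 7 of Hr4 more than 1000 bp from a TSS. The densest 100 kb window (3L, 600001 to 700000, around lncRNA:CR43334) held 12 summits, and 1 on 3R (9500001 to 9600000, around Ras85D and by) held 11. Windows with 9 each lay around ush and cbt (2L, 400001 to 500000), gish and tara (3R, 16200001 to 16300000), part of the Enhancer of split complex (3R, 26000001 to 26100000), chrb (3L, 11400001 to 11500000) and Sik3 and edl (2R, 18600001 to 18700000). When summits at TSSs were placed at random genes and the others uniformly, 54 of 1000 placements had a window with at least 12 (highest 15, median of the highest 9), so clustering beyond gene density was not shown.

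Sequences centred on summits were rich in words with CACTG. Of 8192 words of 7 bases, 43 were more frequent in the 151 bp at the 743 summits away from TSSs than in windows 600 bp to either side, and 5 less. CAGTGTA was found at 8.48% of these summits against 1.28% (6.63-fold, adjusted exact p = 1.98e-12), CACAGTG at 7.40% (4.23-fold) and GCACTGA at 5.92% (4.89-fold), and 13 of the words past the threshold held CACTG on either strand. CACTG was present in 43.9% of summit windows and 21.8% of those 600 bp away, with 2.14-fold more occurrences at summits in the stronger peaks and 1.97-fold in the weaker ones. At TSSs, where composition at summits differed more from the flanks (GC 38.4% against 45.0%), 344 words were more frequent and 359 less, led by TTTAAAA (2.58-fold), ATCGATA (4.60-fold) and CTATCGA (5.93-fold), and the CACTG excess was 1.52-fold.

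Chance among many words was argued against, since 3 words chosen in odd-ranked peaks were 4.51-fold more frequent at summits than beside them in the 371 even-ranked peaks (permutation p = 1e-05, the smallest possible). Per position outside soft-masked sequence the CACTG excess was 1.84-fold (bootstrap 1.57 to 2.14), so it was not confined to soft-masked sequence. A stricter version, in peaks whose windows held no soft-masked base, left 13 peaks (2.8-fold, permutation p = 0.188). It was replaced by the version per position after its result was seen. The choice of CACTG from these same windows favoured a high value, so repeated sequence is not decided by it. For base composition, the CACTG excess was 2.05-fold, while 59 other orders of the same bases had a median of 0.876 and reached at most 1.54. This was the outcome set beforehand against that explanation. CACTG was chosen from words enriched in these same windows, however, which favoured its coming first, so base composition is not decided by this ranking. No factor that binds these words and no biological explanation was tested, since there is 1 group.

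The ratio of replicate 1 to replicate 2 rose with GC content of the 301 bp at the summit (Spearman's rho 0.248 over 2158 optimal peaks; 0.316 at TSSs, 0.170 away from them), with ratios 1.40-fold higher in the 20% of peaks with the highest GC content than in the 20% with the lowest. GC bias between the libraries cannot be told apart from other causes, while the values below argue against noise in weaker peaks. Given the pooled signal, the partial rank correlation was 0.250 (0.210 to 0.289), above the bound of 0.15 set beforehand against noise. GC content hardly varied with signal in these peaks (rho 0.00292), so taking signal out could not change the trend. The partial correlation was therefore set aside after it was seen. The lack of relation itself argues against noise in weaker peaks for these 2158 peaks, since weaker peaks were not of other GC content. By rank, rho was 0.158 in the strongest 500 peaks (interval 0.0712 to 0.242, and 0.0870 away from TSSs), 0.280 in the next 500 and 0.266 in the rest of the strongest 2174. The correlation outside the optimal list was -0.0305 over the 13019 peaks with both values, under the bound of 0.05 set beforehand against GC bias. That bound was set aside after it was seen, because this list holds none of the 2158 peaks above and mixes ranks with and without the trend. The next 2174 peaks by rank had 0.166 (0.255 at TSSs, 0.0680 elsewhere), and ranks 4349 to 10000 had -0.0288.

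Replicate 1 had more peaks at transfer RNA genes: among its 2174 strongest, 17 summits lay at 28 of the 295 genes, against 9 summits at 9 genes in replicate 2. There were 20 genes with a summit in replicate 1 alone and 1 in replicate 2 alone (exact p = 2.10e-05 over genes, which share summits and are not independent). GC bias cannot be told apart from other causes here either: the median log2 ratio at these genes above peaks of like GC content was 0.226 (permutation p = 0.0128), past the bound of 0.2 set beforehand against it, but its bootstrap interval of 0.0535 to 0.479 reached below that bound, a condition added after the value was seen. Reads shared between identical genes also stay open, since genes of unique sequence had a median log2 ratio of 0.175 over 10 peaks, with an interval of -0.305 to 0.634. The median was 0.219 over 47 peaks at genes with identical copies, and -0.0462 at peaks not at transfer RNA genes. No biological explanation was tested for either pattern.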
